A study of Mus musculus with 16 samples.

How the data were processed

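RNA was sequenced from 16 mouse bone marrow samples and given as 1 table of whole-number read counts per Ensembl gene ID, as deposited by the authors, with 45706 gene IDs and 16 columns. Reads were trimmed with Trimmomatic 0.38 and aligned with STAR 2.5.2b to mm10, per the submitters' processing notes, which name the tools without their order or settings. The counting program, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies such as pseudogenes, immunoglobulin segments and globin genes, may be shared. Per the labels' protocols, RNA was extracted with RNeasy Micro columns and libraries were made with either a stranded mRNA kit or a low-input kit; which sample had which is not stated. The protocols describe lineage-negative marrow cells, and the sample labels name LSK cells at Day0 and Day2 and CD45.2 cells at Week2. Each column was matched to a sample by its name.

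Gene symbols, coordinates and classes came from GENCODE M21 (GRCm38, the same build as mm10), which gave a symbol to 45143 of the IDs; 0 lines named no gene. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: TMM scaling, the low count filter filterByExpr with its default settings, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. The 10 LSK libraries were fitted together as 4 groups, the 6 Week2 libraries alone, and all 16 for the difference between the genotype effects at Week2 and Day0. The 3 genotype comparisons, the Day0 to Day2 comparison in each genotype and 2 differences between genotype effects gave 7 comparisons, each adjusted over its own genes. Levels are CPM with TMM scaling, computed from the counts, given as mean and SD of the libraries.

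Before the data were examined, 30 gene lists were fixed, with 454 members, of which 452 matched a symbol (Ahsp and Gpr56 did not). Of these, 29 were tested with limma 3.58.1 as sets of 4 or more tested genes: camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 29 lists. The sex chromosome list was described and not tested. The lists covered stem cell, blood transcription factor partner, mast cell and basophil, erythroid, megakaryocyte and platelet, early granulocyte and monocyte progenitor, late neutrophil granule, monocyte and macrophage, dendritic cell, lymphoid priming, B cell, T and NK cell, and marrow stroma and endothelium genes. They also covered S phase, G2 and mitosis, quiescence, homologous recombination and Fanconi repair, p53 target, type I interferon, interferon gamma and GTPase, inflammatory NF-kB, immediate early, MHC class II, stem cell ageing, oxidative phosphorylation, glycolysis, ribosome biogenesis and MYC, unfolded protein and amino acid stress, and cholesterol synthesis genes. A fold against a group without a count was given as a bound against 3 counts per library; such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

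The rule for named genes was fixed at the same time. It took Gata2 in every comparison and, among called genes whose groups did not overlap, with a mean of 5 CPM or more in the higher group and a proper symbol, the 8 largest rises and 8 largest falls (6 and 6 over time). It added the 3 members of lowest p of each list that passed or held 3 or more called members, the 10 genes of lowest p where fewer than 5 were called, and for differences between effects the 6 of lowest p among called genes. Examples were drawn from these and from the lists' members, so examples beyond the 3 of lowest p were chosen after their values were seen.

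The alternatives were RLE and upper quartile scaling, no low count filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma voom with quality weights, all 16 libraries in 1 fit, the libraries of the groups compared alone, each library left out in turn, and the replicate number as a block. Sex of the library (male where Ddx3y was above 10 CPM), the share of counts on genes of the TEC class, that on the 4 repeat-rich genes (LSK libraries), and protein-coding genes alone were added after the data were seen. Where leaving out a library left a group with 1, its spread was taken from the other groups. Replicates were compared by chi-square over genes with a summed count of 20 or more, and by correlation of log2 CPM with a pseudocount of 1 over genes of 1 CPM or more.

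The procedure was tested on simulated counts with known changes. Each gene was drawn independently from a single mean over all libraries of the fit, with its own spread and the libraries' own sizes. Libraries that stand apart and splits within groups (below) were not simulated, so recovery in the real data may differ. Of genes changed 4-fold, it recovered 47.8% at Day0 (18367 genes), 47.9% at Day2 (18359), 8.7% at Week2 (34692), 34.7% over time in WT (18366), 49% over time in the libraries labelled Gata2 (18396), 18% for the difference between Day2 and Day0 (18375) and 12.2% for that between Week2 and Day0 (30093). Of genes changed 2-fold, it recovered 8.7%, 16.7%, 0%, 8%, 4.08%, 2.17% and 0% in the same order. Total counts were 19.6 M to 68.3 M in LSK libraries and 177 M to 321 M at Week2. Transcript structure, splicing and allele were not analysed here. Some list members entered the tests, but their single values are not reported here.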

Results

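The data were gene-level read counts from 16 RNA sequencing libraries of mouse bone marrow, labelled WT or Gata2. Gata2 encodes a zinc finger transcription factor required by blood stem cells, and the series concerns its haploinsufficiency, the loss of 1 of 2 gene copies, in marrow challenged by transplanting small numbers of sorted cells into irradiated WT recipients. LSK cells (lineage negative, Sca-1 positive, Kit positive), the marrow fraction that holds stem cells and early progenitors, gave 10 libraries: 2 of Day0_WT, 3 of Day0_Gata2, 3 of Day2_WT and 2 of Day2_Gata2. Marrow cells labelled CD45.2, an allelic form of a pan-leukocyte surface protein, gave 3 libraries each of Week2_WT and Week2_Gata2. The labels do not say what was done to the cells between Day0 and Day2. Nothing in the labels says that the libraries of a group came from separate animals. Within Day0_WT, Day0_Gata2 and Week2_Gata2, libraries of opposite sex (below) came from different animals. The p-values measure only the spread between these libraries, which may be technical among libraries of the same sex.

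Total counts were 19.6 and 47.9 M in Day0_WT, 48.7, 48.1 and 68.3 M in Day0_Gata2, 54.8, 51.8 and 53.6 M in Day2_WT, and 51.7 and 53.4 M in Day2_Gata2. At Week2 they were 288, 242 and 257 M in WT and 296, 321 and 177 M in the libraries labelled Gata2. Day0_WT replicate 1, the shallowest library, stood apart: its log2 CPM correlated with that of the other Day0_WT library at r = 0.878 across genes, against 0.986 or more for pairs within the other LSK groups. It had 9.33% of its counts on 4 genes rich in ribosomal or mitochondrial repeat sequence (Gm26917, CT010467.1, Lars2 and Gm23935), against 2.8% to 6.51% in the other LSK libraries. No pair within a group agreed within sampling noise (chi-square per degree of freedom of 28.4 or more), so none was taken for a repeat deposit of 1 library. Sva (chromosome 6, 42038394 to 42042851, plus strand, mm10) was a low gene, higher in every library labelled Gata2 than in any WT library at Day2 and at Week2. Day0_WT replicate 1 had 2.61 CPM of it, against 0 in Day0_WT replicate 2 and 1.94 to 2.42 in the Day0 libraries labelled Gata2. By unscaled CPM, Xist was high and Y-linked Ddx3y near 0 in Day0_WT replicate 2 (399 and 0.104), Day0_Gata2 replicate 3 (282 and 2.02) and Week2_Gata2 replicate 3 (91.9 and 0.0396). The other 13 libraries had Ddx3y between 29.7 and 113, so the sexes were mixed within Day0 and Week2 and not within Day2.

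Gata2 itself (chromosome 6, 88193891 to 88207032, plus strand, mm10) had a mean that was not lower in the libraries labelled Gata2 at any time. Its level was 680 ± 71 CPM (SD, n = 3) in the Day0 libraries labelled Gata2 and 388 ± 82.2 (n = 2) in Day0_WT, a log2 fold change of 0.81 (SE 0.20). At Day2 it was 614 ± 174 (n = 2) against 271 ± 17.6 (n = 3), a log2 fold change of 1.18 (SE 0.19). In both, every library labelled Gata2 lay above every WT library. Over all genes, neither difference passed edgeR's quasi-likelihood test (adjusted p = 0.341 and 0.207). At Week2 the groups overlapped, at 15.9 ± 10.2 and 12.5 ± 1.76 CPM (n = 3 each), with a log2 fold change of 0.35 (SE 0.46, adjusted p = 1). From Day0 to Day2 the log2 fold change was -0.52 (SE 0.19, adjusted p = 0.0705) in WT and -0.15 (SE 0.20, adjusted p = 0.715) in the libraries labelled Gata2. Gata2 passed at Day0 without Day0_WT replicate 2 (adjusted p = 0.033) and at Day2 without Day0_WT replicate 1, which enters the shared spread (0.0352). In WT over time it passed without Day0_WT replicate 2 (0.0277) and without either Day2_Gata2 replicate (0.0259 and 0.0355). Gene-level counts do not show which part of the gene the reads came from. Because the targeted gene was not lower in the libraries labelled Gata2, each direction between genotypes is given as that of the libraries so labelled.

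**Figure D1:**
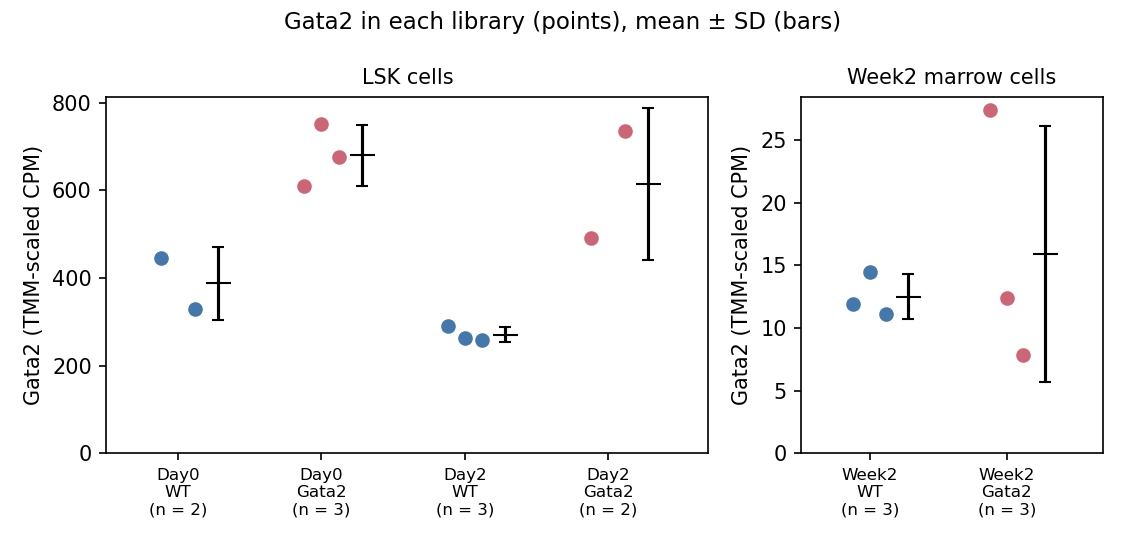
Gata2 level (TMM-scaled counts per M) in each library, with WT in blue and the libraries labelled Gata2 in red; points are libraries and bars the mean ± SD of the group. At Day0 the libraries labelled Gata2 lie between 611 and 752 and WT at 329 and 446; at Week2 the groups overlap.

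At Day0 the comparison asked how the genotypes differed in LSK cells before the interval. Genes of DNA replication were higher on balance in the libraries labelled Gata2 (19 of 21 S phase genes, median log2 fold change 0.38). Mcm4, a subunit of the replicative helicase, stood at 268 ± 20.6 CPM (SD, n = 3) against 187 ± 20.6 (n = 2), and Uhrf1, a factor that maintains DNA methylation, at 415 ± 19.7 against 273 ± 65.2. Ribosome biogenesis and MYC genes were higher in 18 of 18 cases (median 0.16), glycolysis genes in 15 of 16 (median 0.46), oxidative phosphorylation genes in 19 of 20 (median 0.24) and cholesterol synthesis genes in 12 of 14 (median 0.33). These 5 lists passed camera, with adjusted p = 0.175 with an estimated correlation for S phase and for ribosome biogenesis, 0.519 for glycolysis, 0.761 for oxidative phosphorylation and 0.541 for cholesterol synthesis. Of these lists, 8 S phase genes were higher adjusted over the list alone, with 0 genes of the other 4 lists and 0 over all genes. The medians rested on the Day0_WT libraries. Without Day0_WT replicate 1 they were 0.23 for S phase, 0.16 for glycolysis, 0.06 for oxidative phosphorylation (adjusted p = 0.0671) and 0.15 for cholesterol synthesis. Without Day0_WT replicate 2 they were 0.64, 1.11, 0.70 and 0.98 in the same order and 0.34 for ribosome biogenesis, which had 0.27 without Day2_Gata2 replicate 1 and 0.10 with RLE scaling. Measures of the libraries also parted the genotypes: the repeat-rich genes took 6.51% and 9.33% of counts in Day0_WT and 5.1% to 5.83% in the libraries labelled Gata2. TEC genes (loci awaiting experimental evidence) took 0.187% and 0.362% against 0.131% to 0.159%, and 22150 and 26159 genes had a count against 28286 to 30564. The TEC and repeat shares were each added as a covariate, chosen after the data were seen. In this order the medians were then 0.21 and 0.25 for S phase, 0.01 (adjusted p = 0.559) and 0.07 for glycolysis. They were -0.03 (0.755) and -0.08 (0.145) for oxidative phosphorylation and 0.02 (0.422) and 0.12 (0.178) for cholesterol synthesis.

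Stem cell genes were lower at Day0 in 13 of 18 cases (median log2 fold change -0.22), among them the transcription factor genes Hoxa9 (71.1 ± 5.09 CPM, SD, n = 3, against 117 ± 11.1, n = 2) and Hlf (128 ± 17.8 against 218 ± 35.6). Quiescence genes (11 of 14 lower, median -0.30) and immediate early genes (9 of 13 lower, median -0.28) also passed camera as lower, with Nr4a1, an orphan nuclear receptor, at 69.2 ± 18.2 against 230 ± 51.7. The calls were lost with the estimated correlation: adjusted p = 0.293 with an estimated correlation for stem cell, 0.379 for quiescence and 0.72 for immediate early genes. When adjusted over the list alone, 4 stem cell, 1 quiescence and 1 immediate early genes were lower and 1 quiescence gene, Adgrg1, was higher (2240 ± 238 against 1550 ± 310), and over all genes 0 passed. By fry, S phase and ribosome biogenesis passed (adjusted p = 0.0289 each). Medians of the stem cell, quiescence and immediate early lists were 0.14, -0.06 and 0.25 without Day0_WT replicate 2 and -0.36, -0.19 and -0.46 without Day0_WT replicate 1. Stem cell had -0.13 without Day2_Gata2 replicate 1 and -0.37 without Day0_Gata2 replicate 2. Quiescence had -0.19 without Day2_Gata2 replicate 1 and -0.20 without Day0_Gata2 replicate 3. Immediate early had -0.52 and -0.10 without Day0_Gata2 replicate 2 or 3. With the TEC and the repeat share as covariates, quiescence had -0.12 and -0.01 (adjusted p = 0.0804 for the latter) and immediate early -0.66 and -0.51. Stem cell had -0.45 with the TEC share.

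The lists lower at Day0 rested on Day0_WT replicate 2, while the medians of the higher lists grew without it. Without that library, adjusted p was 0.828 for stem cell, 0.69 for quiescence, 0.875 for immediate early and 0.0512 for cholesterol synthesis, whose median rose to 0.98, and 5 lists passed in place of 8, against 15 without Day0_WT replicate 1. Oxidative phosphorylation lost its call without Day0_WT replicate 1 (0.0671) or Day0_Gata2 replicate 1 (0.0527), immediate early without Day0_Gata2 replicate 3 (0.0678) and quiescence without Day2_Gata2 replicate 1 (0.0565). Of 19162 genes edgeR called 0, with 2586 at an unadjusted p under 0.05; DESeq2 called 417 (38 higher, 379 lower), limma voom 0 and edgeR with no low count filter 1. Without Day0_WT replicate 2, which left the library that stood apart as the Day0_WT group, edgeR called 8655. Nr4a1 had the lowest p (log2 fold change -1.73, SE 0.25, adjusted p = 0.341), followed by the chemokine gene Ccl3 (-1.15, SE 0.20, adjusted p = 0.341). Groups did not overlap for 32.6% of genes, against 20% by chance.

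The other 21 lists did not pass at Day0. Late neutrophil granule genes had a median log2 fold change of 0.71 (adjusted p = 0.106), early granulocyte and monocyte progenitor 0.37 (0.249), G2 and mitosis 0.29 (0.106), p53 target 0.21 (0.822), interferon gamma and GTPase 0.20 (0.284), homologous recombination and Fanconi repair 0.15 (0.229) and unfolded protein and amino acid stress 0.14 (0.473). Marrow stroma and endothelium stood at -0.31 (0.351), stem cell ageing at -0.30 (0.351), B cell at -0.25 (0.797), mast cell and basophil at -0.22 (0.615), dendritic cell at -0.20 (0.315), inflammatory NF-kB at -0.12 (0.0954) and blood transcription factor partners at -0.11 (0.273). Monocyte and macrophage (-0.09, 0.531), T and NK cell (-0.03, 0.797), type I interferon (-0.03, 0.797), erythroid (-0.03, 0.229) and MHC class II (0.01, 0.943) lists lay near 0. Lymphoid priming had a negative median (-0.17) with a positive mean (0.07) and test (adjusted p = 0.6), and megakaryocyte and platelet a positive median (0.02) with a negative mean (-0.12) and test (0.307). Among them, 3 megakaryocyte, 2 dendritic cell and 2 NF-kB genes were lower adjusted over the list alone, and 0 over all genes.

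At Day2 the libraries labelled Gata2 had lower levels of glycolysis genes: all 16 of the list were lower, with a median log2 fold change of -0.75. Slc16a3, which exports lactate, stood at 150 ± 2.4 CPM (SD, n = 2) against 345 ± 27.5 in WT (n = 3), Pfkl, a phosphofructokinase, at 537 ± 30.2 against 936 ± 66.7, and Eno1, an enolase, at 1700 ± 96.7 against 3320 ± 299. The inflammatory NF-kB list was also lower, in 14 of 16 genes (median -0.84), including the chemokine gene Ccl4 (2.83 ± 0.15 against 9.57 ± 2.22), Nfkbia, an inhibitor of NF-kB (53.2 ± 3.3 against 110 ± 3.35), and Tnfaip3, which restrains NF-kB signalling (19.8 ± 4.91 against 42.4 ± 4.06). Both lists passed camera and kept that call with an estimated correlation (adjusted p = 0.0467 for glycolysis and 0.0139 for NF-kB). By fry, a separate test, they passed too (adjusted p = 0.0104 and 0.00239). In these lists 13 glycolysis genes and 7 NF-kB genes were lower adjusted over the list alone, and 0 over all genes. Both lists also passed in each fit that left out 1 of the 10 LSK libraries and with the TEC or the repeat share as a covariate. The Day0 libraries among the 10 enter this comparison only through the shared fit. The TEC share differed between the Day2 groups without overlap (0.0648% and 0.0702% against 0.0314% to 0.0582%). The fit with that share therefore cannot part a genotype difference from one with this library measure.

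**Figure D2:**
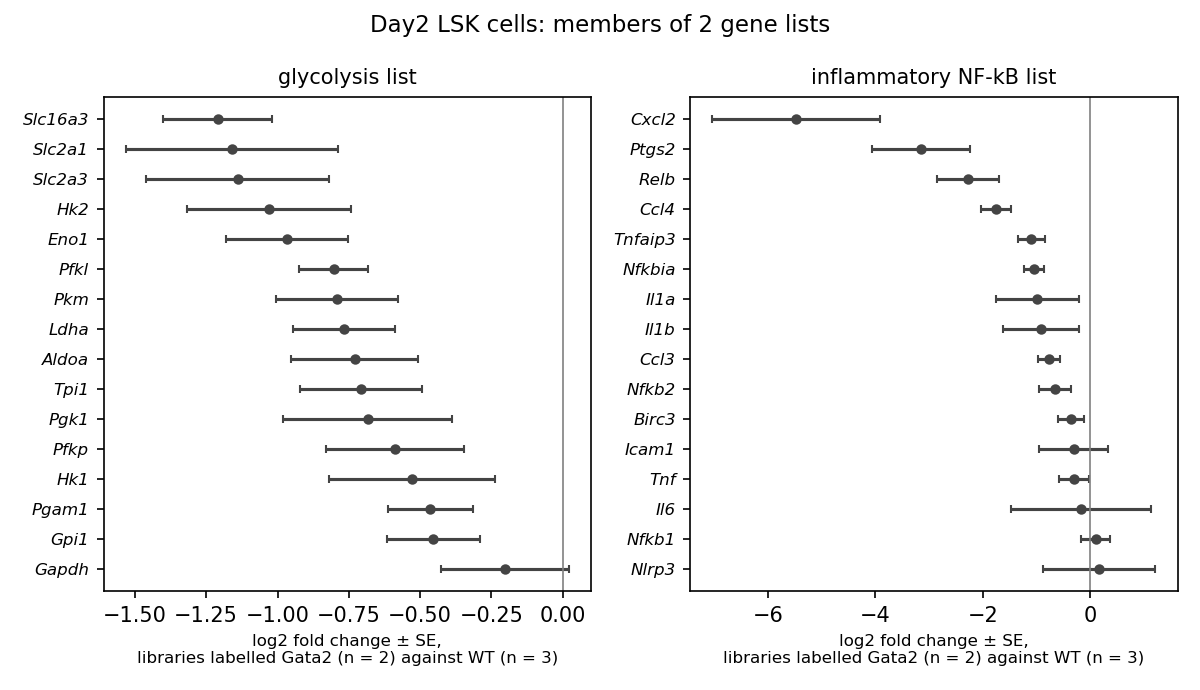
log2 fold change (± SE) of each member of the glycolysis and NF-kB lists at Day2, libraries labelled Gata2 (n = 2) against WT (n = 3); the vertical line marks no difference. All 16 glycolysis genes lie below 0, from Gapdh at -0.20 to Slc16a3 at -1.21, and 14 of 16 NF-kB genes do.

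Another 9 lists passed at Day2 with the preset correlation. Immediate early genes had a median log2 fold change of -0.71 (11 of 13 lower), with Ier3, a stress-responsive survival gene, at 30.3 ± 3.22 CPM (SD, n = 2) against 85.1 ± 4.45 (n = 3) and Jun at 19.8 ± 0.533 against 45.2 ± 5.45. Stem cell ageing genes had a median of -0.56 (16 of 21 lower), including the metallothionein genes Mt2 (0.494 ± 0.224 against 10.5 ± 2.81) and Mt1 (85.3 ± 25.5 against 189 ± 27). Medians were -0.36 for p53 targets (13 of 18 lower), -0.31 for MHC class II (9 of 10), -0.26 for cholesterol synthesis (13 of 14), -0.24 for unfolded protein and amino acid stress (12 of 14), -0.21 for megakaryocyte and platelet (11 of 14) and -0.19 for stem cell genes (15 of 18). Lymphoid priming genes were higher in 8 of 10 cases (median 0.30, or 0.18 with a member that had no count in a group at its bound), with the DNA polymerase gene Dntt at 45.4 ± 2.13 against 26 ± 0.926 and the lymphotoxin gene Ltb lower, at 6.66 ± 0.581 against 22.1 ± 9.91. These 9 calls were lost with the estimated correlation: adjusted p = 0.173 with an estimated correlation for amino acid stress, ageing, cholesterol, p53 and megakaryocyte lists, 0.258 for stem cell and lymphoid priming, and 0.298 for immediate early and MHC class II. With p adjusted over the list alone, 4 immediate early, 2 ageing, 2 MHC class II and 1 amino acid stress genes were lower, and 1 lymphoid priming gene was higher and 1 lower; over all genes 0 passed. Stem cell lost its preset call without Day2_WT replicate 1 (adjusted p = 0.133) or Day2_Gata2 replicate 1 (0.274, median -0.10), megakaryocyte without Day2_Gata2 replicate 1 (0.365, median 0.01) or Day2_WT replicate 2 (0.0829) and MHC class II without Day2_WT replicate 3 (0.127, median -0.19). Lymphoid priming lost it without Day2_WT replicate 1 (0.08) or 2 (0.0929) or Day2_Gata2 replicate 1 (0.0835, median 0.56) or 2 (0.0793, median 0.15). Medians that moved with the call kept were -0.50 for cholesterol without Day2_Gata2 replicate 1, -0.21 for p53 and -0.40 for megakaryocyte without Day2_Gata2 replicate 2, -0.45 for immediate early without Day2_WT replicate 1 and -0.28 for stem cell without Day2_WT replicate 3. With the TEC share as a covariate, medians were -0.09 for cholesterol, -0.42 for immediate early, -0.17 for ageing, -0.16 for amino acid stress and 0.19 for lymphoid priming genes (adjusted p = 0.181).

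The single gene of lowest adjusted p at Day2 was Ier3 (0.0572, log2 fold change -1.49, SE 0.16). Hmox1, the inducible heme oxygenase, stood at 3.87 ± 2.74 CPM (SD, n = 2) against 144 ± 18.2 (n = 3; -5.22, SE 0.60, adjusted p = 0.0828), and Ddit4, a stress-induced inhibitor of mTORC1, at 8.57 ± 2.58 against 37 ± 3.68 (-2.11, SE 0.26, adjusted p = 0.0991). Bnip3, a mitophagy receptor, stood at 69.2 ± 5.98 against 247 ± 33.5, and Ankrd37 at 4.52 ± 0.341 against 24.3 ± 5.63. Of 19162 genes edgeR called 0, with 1070 at an unadjusted p under 0.05; DESeq2 called 144 (43 higher, 101 lower), limma voom 23, edgeR with no low count filter 22 and edgeR on the 5 Day2 libraries alone 11. Hmox1 and Ier3 were each called in 9 of 13 alternatives, not counting the fits that left out 1 library in turn. For both, the TEC share as a covariate was among the 9, with 17 genes called. Without Day0_WT replicate 1 or 2, which enter this comparison through the shared spread, edgeR called 48 and 32. Groups did not overlap for 21.1% of genes, against 20% by chance, nor in the share of TEC genes, at 0.0648% and 0.0702% in the libraries labelled Gata2 and 0.0314% to 0.0582% in WT.

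The other 18 lists did not pass at Day2. B cell genes were nearest (11 of 14 higher, median log2 fold change 1.47, or 0.60 with 6 members that had no count in a group at their bounds; adjusted p = 0.0518), and adjusted over the list alone 1 gene was higher. Monocyte and macrophage genes had a median of -0.35 (adjusted p = 0.0826), quiescence -0.32 (0.151), late neutrophil granule -0.23 with a mean of 0.11 (0.0605), dendritic cell -0.21 with a positive test (0.971), type I interferon -0.08 (0.331), early granulocyte and monocyte progenitor -0.05 (0.551) and mast cell and basophil -0.04 (0.795). Blood transcription factor partners (0.11, 0.133), G2 and mitosis (0.11, 0.133), homologous recombination and Fanconi repair (0.09, 0.289), ribosome biogenesis and MYC (0.04, 0.778), S phase (0.00, 0.316), oxidative phosphorylation (-0.02, 0.444) and interferon gamma (-0.03, 0.971) lists lay near 0. T and NK cell (adjusted p = 0.51) and stroma (0.551) lists had medians of 0, the latter with a mean of 0.13 and a negative test. Erythroid genes had a median of 0.00 (-0.01 with bounds), a mean of 0.47 and a negative test (0.971).

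The difference between the genotype effects at Day2 and Day0 was tested directly. Glycolysis genes were on balance higher at Day0 and lower at Day2 in the libraries labelled Gata2, and 16 of 16 had a negative difference (median log2 difference -1.16); Slc16a3 had the lowest p of all genes (-1.86, SE 0.27, adjusted p = 0.465). The list passed camera and fry (adjusted p = 2.8e-19 and 0.0171), with adjusted p = 0.273 with an estimated correlation. Adjusted over the list alone 14 genes were lower, and 0 over all genes. This list test was not repeated with a library left out or with a covariate. edgeR called 0 genes for the difference, with 1984 at an unadjusted p under 0.05; DESeq2 called 216, edgeR with no low count filter 2 and limma voom 0, and without Day0_WT replicate 2 edgeR called 6733. Upper quartile scaling moved the median difference of all genes by 0.108. Across 19162 genes, which are not independent replicates, the log2 fold changes of the genotype comparisons at Day0 and Day2 had a Pearson r of -0.00395 and a Spearman rho of -0.0601.

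From Day0 to Day2, edgeR called 5720 of 19162 genes in WT LSK cells, 2286 higher and 3434 lower at Day2. For this interval, in both genotypes, counts of a list's genes that rose or fell are of called genes, except where adjusted over the list alone. Genes that were not called may have moved as well. Glycolysis genes rose (all 16, median log2 fold change 2.16), as did cholesterol synthesis genes (all 14, median 2.34) and 11 of 14 megakaryocyte and platelet genes (median 2.76). Slc16a3 went from 9.48 ± 3.08 CPM (SD, n = 2) to 345 ± 27.5 (n = 3), Cyp51, a sterol demethylase, from 28.5 ± 3.4 to 207 ± 17.2, and Pf4, a platelet chemokine gene, from 48.3 ± 21.4 to 957 ± 176. Immediate early genes fell (10 of 13, median -4.20), with Fos from 2020 ± 624 to 8.92 ± 1.34 and Jun from 1950 ± 723 to 45.2 ± 5.45, as did type I interferon genes (19 of 23, median -2.15), with the antiviral gene Oas2 from 61.4 ± 30.3 to 1.13 ± 0.185, and lymphoid priming genes (9 of 10, median -2.04), with Dntt from 244 ± 0.194 to 26 ± 0.926. Megakaryocyte and cholesterol lists kept their call with an estimated correlation (adjusted p = 0.0272 and 0.0337), while glycolysis had adjusted p = 0.0704 with an estimated correlation, immediate early 0.131, type I interferon 0.125 and lymphoid priming 0.0569. Adjusted over the list alone, 16 glycolysis, 14 cholesterol and 12 megakaryocyte genes rose and 11 immediate early, 20 type I interferon and 9 lymphoid priming genes fell. Measures of the libraries moved with the day in both genotypes. The 4 repeat-rich genes took 5.1% to 9.33% of counts at Day0 and 2.8% to 4.39% at Day2, TEC genes 0.131% to 0.362% and 0.0314% to 0.0702%, and 22150 to 30564 and 19266 to 21944 genes had a count. With the TEC share as a covariate edgeR called 2358 genes in WT, 808 of them among the 5720, and with the repeat share 173, of which 151 were among them. The glycolysis median was then 1.40 with the TEC share, and that of lymphoid priming -1.17 and -1.27 with the TEC and the repeat share. Gata2 itself had log2 fold changes of 0.05 (SE 0.38) and 0.13 (SE 0.39) with these covariates, in place of -0.52 (SE 0.19). Both shares differed between the days without overlap, so these fits cannot part a change with the day from one with the library measures.

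The libraries labelled Gata2 had 1782 genes called over the same interval, 858 higher and 924 lower, against 349 and 1146 with no low count filter and 371 and 842 with all 16 libraries in 1 fit. Megakaryocyte and platelet genes rose (10 of 14, median log2 fold change 2.62), with Ppbp, a platelet chemokine gene, from 0.961 ± 0.0588 CPM (SD, n = 3) to 149 ± 12.5 (n = 2), as did cholesterol synthesis genes (12 of 14, median 1.94) and glycolysis genes (12 of 16, median 1.14). Immediate early genes fell (11 of 13, median -4.16), as did 14 of 23 type I interferon genes (median -2.28) and 5 of 10 lymphoid priming genes (median -1.69). Megakaryocyte, cholesterol and lymphoid priming lists kept their call with an estimated correlation (adjusted p = 0.0082, 0.0241 and 0.0299), and glycolysis, immediate early and type I interferon had adjusted p = 0.0875 with an estimated correlation. Adjusted over the list alone, 13 megakaryocyte, 12 cholesterol and 14 glycolysis genes rose and 11 immediate early, 21 type I interferon and 10 lymphoid priming genes fell. Of the genes called in each genotype, 748 were higher and 788 lower in both, against 102 and 166 for independent lists, and 1 was called in opposite directions. The comparisons share no library, but both use each gene's spread from the 1 fit of all LSK libraries. A gene of low spread is thus more readily called in both, so the numbers for independent lists are no test of the overlap. Any difference in handling between the days also enters both. With the TEC share as a covariate 5031 genes were called, 1693 of them among the 1782, and with the repeat share 2066, of which 1051 were among them. The repeat share gave medians of 1.22 for cholesterol and -1.11 for lymphoid priming genes. Across genes, the log2 fold changes correlated at Pearson r = 0.703 and Spearman rho = 0.639.

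**Figure D3:**
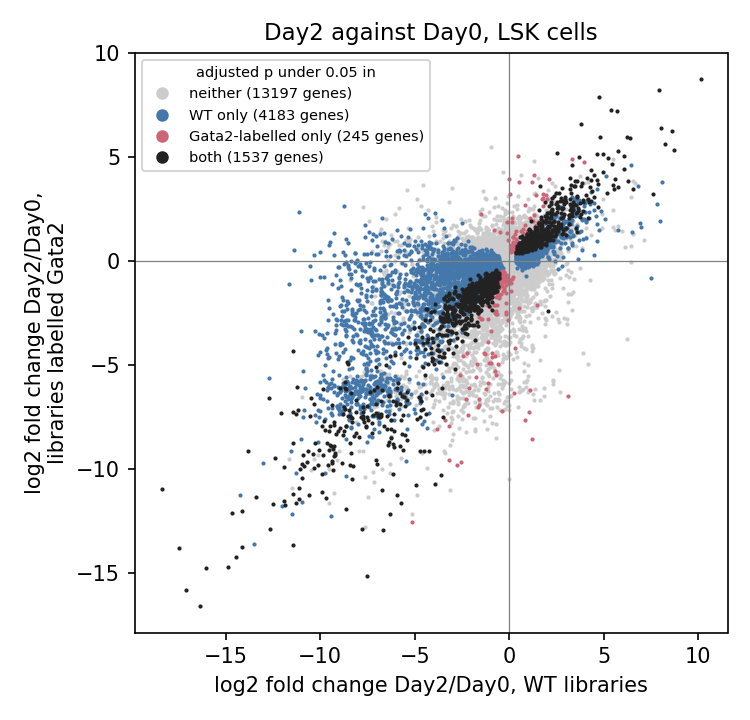
log2 fold change from Day0 to Day2 of each of 19162 genes in WT (x axis) and in the libraries labelled Gata2 (y axis), coloured by the comparison in which edgeR's adjusted p was under 0.05. Of the 1537 genes called in both, 1 was called in opposite directions.

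Lists of division, translation and stress passed camera as higher over the interval, with part of their genes called. G2 and mitosis genes rose in WT and in the libraries labelled Gata2 (14 and 6 of 20, median log2 fold changes 0.97 and 0.72), with Ccnb1, a mitotic cyclin, from 86.3 ± 41.2 to 318 ± 17 CPM in WT (SD, n = 2 and 3). Unfolded protein and amino acid stress genes rose (10 and 6 of 14, medians 0.91 and 0.56), with Asns, asparagine synthetase, from 21.6 ± 6.63 to 302 ± 19.1 in WT, while Ddit4 fell in the libraries labelled Gata2. With an estimated correlation, G2 and mitosis had adjusted p = 0.177 and 0.1, and amino acid stress 0.107 and 0.1. Ribosome biogenesis and MYC genes rose (11 and 4 of 18, medians 0.58 and 0.29) and kept their call with an estimated correlation (adjusted p = 0.0289 and 0.0299). Oxidative phosphorylation genes (12 and 4 of 20, medians 0.73 and 0.27) and p53 targets (8 and 4 of 18, medians 0.70 and 0.35, with Plk2 falling in WT) rose, the latter including Perp, a p53-induced membrane protein gene, from 1.86 ± 0.719 to 20 ± 1.66 in WT. With an estimated correlation, oxidative phosphorylation had adjusted p = 0.203 and 0.22, and p53 targets 0.107 and 0.1. S phase genes rose in WT (11 of 21, 2 fell, median 0.52) and did not pass in the libraries labelled Gata2 (3 rose, 3 fell, median 0.20, adjusted p = 0.0632). The WT call had adjusted p = 0.159 with an estimated correlation, and the difference between genotypes had a median of -0.39 (adjusted p = 0.00396, and 0.359 with an estimated correlation). Adjusted over the list alone, by WT and then the libraries labelled Gata2, 17 and 16 G2 and mitosis, 10 and 9 amino acid stress, 12 and 6 ribosome biogenesis, 15 and 7 oxidative phosphorylation, 11 and 5 p53 target and 12 and 3 S phase genes rose. Without Day0_WT replicate 1 the WT medians were 0.58 for G2 and mitosis, 0.47 for oxidative phosphorylation and 0.30 for S phase. Without Day0_WT replicate 2 those of the libraries labelled Gata2 were 0.15 for ribosome biogenesis, 0.13 for oxidative phosphorylation and 0.23 for p53 targets. With the TEC and the repeat share as covariates, WT medians were 0.21 and 0.41 for G2 and mitosis, 0.43 and 0.39 for amino acid stress, and 0.34 and 0.32 for ribosome biogenesis. They were 0.11 (adjusted p = 0.179) and 0.03 (0.426) for oxidative phosphorylation and 0.12 (0.257) and 0.10 (0.172) for S phase. In the libraries labelled Gata2 they were 0.44 for G2 and mitosis, 0.35 for amino acid stress and 0.10 (0.323) for oxidative phosphorylation with the repeat share.

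Late neutrophil granule genes rose as well (9 of 13 in WT and 4 of 13 in the libraries labelled Gata2, median log2 fold changes 3.24 and 1.78), with Chil3, a chitinase-like protein gene, from 22.7 ± 10.8 to 214 ± 69.1 CPM in WT (SD, n = 2 and 3). So did stem cell ageing genes (7 and 6 of 21, medians 1.17 and 0.86, with 2 and 1 falling), where Mt1 went from 32 ± 0.659 to 189 ± 27 in WT. The ageing median in WT was 0.51 without Day0_WT replicate 1 and 2.59 without Day0_WT replicate 2, and that of the libraries labelled Gata2 was 0.52 without Day2_Gata2 replicate 1. The homologous recombination and Fanconi repair list passed camera as higher (medians 0.35 and 0.28), with 3 of 15 genes called in WT and 0 in the libraries labelled Gata2. Late neutrophil had adjusted p = 0.225 and 0.168 with an estimated correlation, ageing 0.198 and 0.16, and repair 0.203 and 0.149. The genes that rose adjusted over the list alone numbered 9 and 7 for late neutrophil, 8 and 7 for ageing and 7 and 0 for repair. The repair list lost its preset call in WT without Day2_WT replicate 1 (adjusted p = 0.0635) or Day0_WT replicate 2 (0.0546), and in the libraries labelled Gata2 without Day2_Gata2 replicate 1 (0.112, median 0.17), where its median was 0.14 without Day0_WT replicate 2. In WT it also lost the call with sex (adjusted p = 0.0803) or the TEC share (0.119) as a covariate. With the TEC and the repeat share, late neutrophil medians were 0.92 (adjusted p = 0.051) and 0.42 (0.0543) in WT and 0.88 and 0.49 (0.0792) in the libraries labelled Gata2. Those of ageing genes were 0.31 (0.172) and 0.34 in WT, where sex gave 2.22, and 0.24 and 0.35 in the libraries labelled Gata2.

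Stem cell genes fell over the interval (9 of 18 in WT and 6 of 18 in the libraries labelled Gata2, median log2 fold changes -0.95 and -0.53), with Hoxa9 from 117 ± 11.1 to 39.9 ± 1.56 CPM in WT (SD, n = 2 and 3) and Procr, a stem cell surface receptor gene, from 21.8 ± 5.03 to 2.39 ± 1.15 in the libraries labelled Gata2 (n = 3 and 2). Quiescence genes fell (6 and 4 of 14, medians -0.79 and -0.39), with the transcription factor gene Klf2 from 350 ± 79.2 to 40.3 ± 8.13 in WT, while Cdkn1a, a cell cycle inhibitor gene, rose in WT. With an estimated correlation, stem cell had adjusted p = 0.157 and 0.168, and quiescence 0.159 and 0.168. Interferon gamma and GTPase genes fell (7 and 5 of 16, medians -0.31 and -0.81), with Irgm1, an immunity-related GTPase gene, from 114 ± 1.22 to 53.5 ± 3.2 in WT, while Ifi47 rose in WT. That list had adjusted p = 0.254 and 0.1 with an estimated correlation. Those that fell adjusted over the list alone numbered 10 and 7 for stem cell, 9 and 5 for quiescence and 7 and 10 for interferon gamma. Without Day0_WT replicate 2 the WT calls were lost for stem cell (adjusted p = 0.183), quiescence (0.11) and interferon gamma (0.712, median 0.01), whose median was -0.80 without Day0_WT replicate 1 and -0.57 without Day2_WT replicate 3. Interferon gamma also lost it without Day2_WT replicate 1 (0.0623), Day2_Gata2 replicate 1 (0.0763) or 2 (0.0806) or Day0_Gata2 replicate 3 (0.0568) and with sex as a covariate (0.198), and quiescence lost it in the libraries labelled Gata2 without Day2_Gata2 replicate 1 (0.0572). With the TEC and the repeat share as covariates, quiescence lost its call in WT (0.119 and 0.141, the latter with a median of -0.42) and in the libraries labelled Gata2 (0.105 and 0.168). Stem cell lost it in the latter with the repeat share (0.0722), and interferon gamma medians in WT were -0.93 and -1.03, against -0.13 with sex.

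Lists of lymphoid and erythroid markers passed camera as lower over the interval, with part of their genes called. B cell genes fell in WT and in the libraries labelled Gata2 (11 and 5 of 14, median log2 fold changes -6.12 and -3.83), as did T and NK cell genes (7 and 6 of 14, medians -3.02 and -4.45). Erythroid genes fell (9 and 4 of 18, medians -3.61 and -1.95), where Car1, a carbonic anhydrase gene, went from 102 ± 33.5 to 0.332 ± 0.159 CPM in WT (SD, n = 2 and 3) while Tfrc, the transferrin receptor gene, rose from 37.4 ± 11.3 to 343 ± 30.9. With an estimated correlation, B cell had adjusted p = 0.107 and 0.0875, T and NK cell 0.115 and 0.0875, and erythroid 0.238 and 0.307. With members that had no count in a group at their bounds, the medians were -5.22 in WT for B cell, -2.52 and -3.24 for T and NK cell and -2.64 in WT for erythroid genes. Igha, an immunoglobulin heavy chain gene outside the lists, was at 858 ± 211 CPM in Day0_WT and had no count in Day2_WT, at least 15300-fold lower against 3 counts per library. Adjusted over the list alone, 13 and 13 B cell, 8 and 12 T and NK cell and 12 and 5 erythroid genes fell. Without Day0_WT replicate 2 the WT calls were lost for erythroid (adjusted p = 0.183, median -1.80) and T and NK cell genes (0.0546, median -1.25). In the libraries labelled Gata2 the erythroid call was lost without Day2_Gata2 replicate 1 (0.11, median -1.07) or Day0_WT replicate 1 (0.0507) or 2 (0.0951). There the fitted medians without Day2_Gata2 replicate 2, which are no bounds, were -8.04 for B cell, -6.77 for T and NK cell and -5.87 for erythroid genes.

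MHC class II, stroma and NF-kB lists passed as lower in the libraries labelled Gata2 and did not pass in WT. MHC class II genes fell (4 of 10, median log2 fold change -1.08), including Cd74, the invariant chain gene, from 195 ± 25.8 to 61.7 ± 3.65 CPM (SD, n = 3 and 2). Marrow stroma and endothelium (1 of 9 fell, median -2.38, or -1.53 with bounds) included the chemokine gene Cxcl12, from 11.3 ± 1.78 to 0.118 ± 0.0557, and NF-kB (4 of 16 fell, 1 rose, median -0.76) included Ccl4, from 73.4 ± 20.7 to 2.83 ± 0.15. These had adjusted p = 0.149, 0.168 and 0.142 with an estimated correlation. In WT the medians were -0.51 (3 fell, adjusted p = 0.0917), -1.31 (3 fell, 1 rose, 0.0973) and -0.40 with a mean of 0.06 (2 fell, 2 rose, 0.888). The differences between genotypes had adjusted p = 0.0701, 0.766 and 0.0253, the last with adjusted p = 0.284 with an estimated correlation. Adjusted over the list alone, by WT and then the libraries labelled Gata2, 4 and 4 MHC class II, 3 and 1 stroma and 2 and 5 NF-kB genes fell. The stroma median was -4.92 without Day2_Gata2 replicate 2, and its call was lost without Day2_Gata2 replicate 1 (adjusted p = 0.182) or Day0_WT replicate 1 (0.124) or 2 (0.122). The NF-kB call was lost with RLE scaling (adjusted p = 0.051), with sex as a covariate (0.0823) and without Day2_Gata2 replicate 1 (0.112) or 2 (0.0926), Day0_Gata2 replicate 3 (0.078) or Day2_WT replicate 1, 2 or 3 (0.0522, 0.0543 and 0.0533). Both calls were lost with the TEC or the repeat share as a covariate, with adjusted p = 0.27 and 0.162 for stroma and 0.0642 and 0.0752 for NF-kB.

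**Figure D4:**
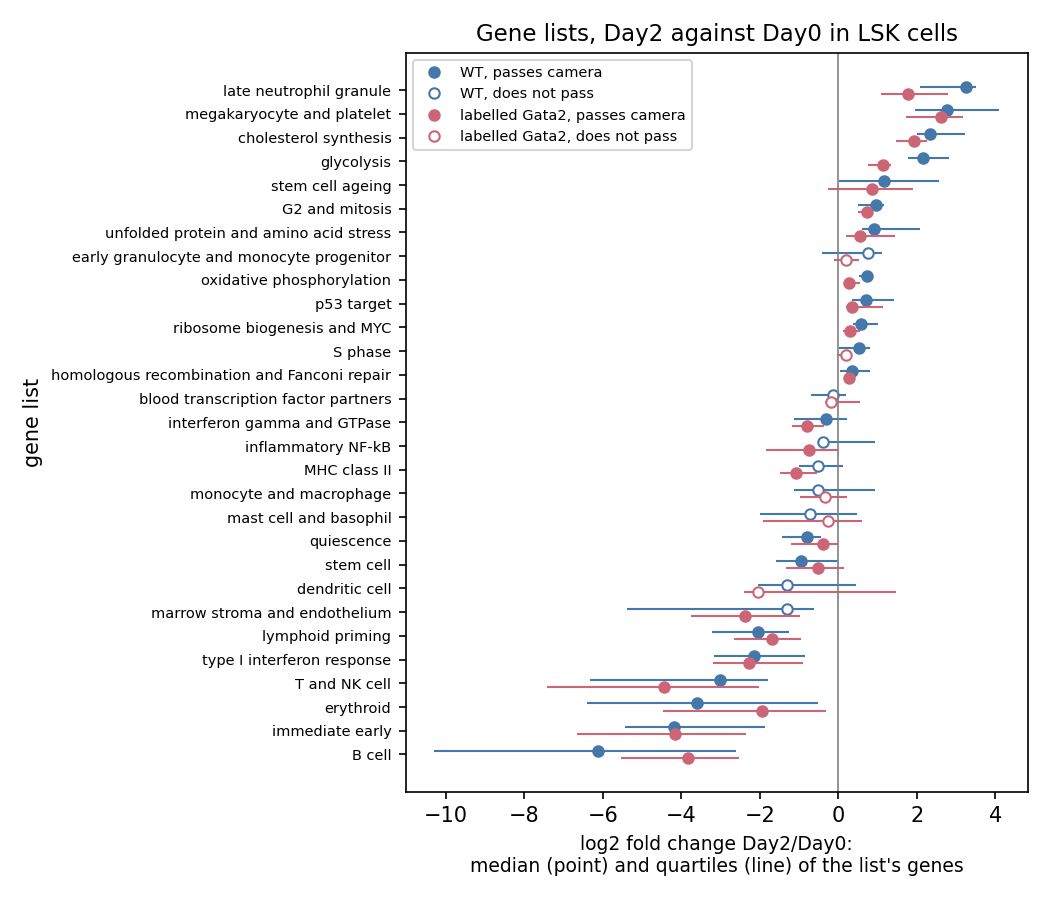
Median (point) and quartiles (line) of the log2 fold change from Day0 to Day2 over the tested genes of each of 29 lists, WT in blue and libraries labelled Gata2 in red; filled points pass camera with the preset correlation. Glycolysis has a median of 2.16 in WT and 1.14 in the libraries labelled Gata2, and immediate early genes -4.20 and -4.16.

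The remaining 5 lists passed in neither genotype, with members going both ways. In the monocyte and macrophage list (medians -0.52 in WT and -0.33 in the libraries labelled Gata2) Ccr2, a chemokine receptor gene, rose from 27.3 ± 9.7 to 262 ± 15.3 CPM in WT (SD, n = 2 and 3) and Klf4 fell from 36 ± 3.87 to 1.95 ± 0.326. In the dendritic cell list (medians -1.30 and -2.06) Flt3, a cytokine receptor gene, fell from 501 ± 77.1 to 89.6 ± 18.2 and Siglech rose. In the mast cell and basophil list (medians -0.73 and -0.26) the protease gene Mcpt8 fell from 77.2 ± 24.1 to 26.1 ± 6. Early granulocyte and monocyte progenitor genes had medians of 0.75 and 0.20, and blood transcription factor partners -0.14 and -0.19, the latter with a mean of 0.02 and a positive test; Zfpm1, which encodes a GATA cofactor, fell from 189 ± 32.3 to 33.8 ± 12.9 in WT. By WT and then the libraries labelled Gata2, genes that fell numbered 2 and 2 for monocyte, 3 and 2 for dendritic cell, 4 and 2 for mast cell, 2 and 2 for early granulocyte and 6 and 2 for transcription factor lists. Those that rose numbered 2 and 1, 1 and 2, 1 and 1, 2 and 1, and 2 and 2. Counted as adjusted over the list alone, 2 and 3, 3 and 4, 5 and 4, 3 and 3, and 6 and 3 fell, and 2 and 1, 1 and 2, 1 and 2, 4 and 1, and 2 and 3 rose.

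Of the 29 lists, 21 passed in WT and 23 in the libraries labelled Gata2, with 3 and 4 holding with an estimated correlation and 25 and 23 passing by fry. The split of calls in WT depended on the scaling and on the genes and libraries that entered: 40% were higher with TMM and 28.7% with the upper quartile, which moved the median log2 fold change of all genes by -0.156. It was 21.9% with no low count filter, 28% with all 16 libraries in 1 fit and 25.8% without Day2_Gata2 replicate 1. In the libraries labelled Gata2 it was 48.1%, and 23.3% with no low count filter, 30.6% with all 16 libraries and 33.7% without Day0_WT replicate 2. The count in WT was 1355 by limma voom and 1199 with the 5 libraries of WT alone, 3191 without Day2_WT replicate 2, 3338 without Day2_WT replicate 3 and 12386 without Day0_WT replicate 2. Sex moved with time in WT, where Xist fell (log2 fold change -13.04, SE 3.62, adjusted p = 0.0256). It moved in part in the libraries labelled Gata2 as well. There Xist was at 282 unscaled CPM in Day0_Gata2 replicate 3 and at 0.135 and 0.0749 in the Day2_Gata2 libraries. In the libraries labelled Gata2 the count was 3471 by DESeq2, 4127 by limma voom and 5676 with their 5 libraries alone. It was 499 and 804 without Day2_Gata2 replicate 1 or 2, 862, 698 and 783 without Day0_Gata2 replicate 1, 2 or 3, and 4863 and 4606 without Day0_WT replicate 1 or 2. Groups did not overlap for 51.5% of genes in WT and 60.3% in the libraries labelled Gata2, against 20% by chance.

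At Week2 the comparison asked how marrow cells labelled CD45.2 differed between genotypes. Monocyte and macrophage genes were higher on balance in the libraries labelled Gata2 (14 of 16, median log2 fold change 0.29), where the complement genes C1qa and C1qb stood at 12.8 ± 11 and 23.4 ± 20.5 CPM (SD, n = 3) against 2.31 ± 2.2 and 3.65 ± 4.3 (n = 3). MHC class II genes were higher in 10 of 10 cases (median 0.44), with H2-Eb1 at 163 ± 102 against 87.5 ± 44.4, and interferon gamma and GTPase genes in 16 of 16 (median 0.42). These levels followed a split of the libraries that was not by label. H2-Eb1 was at 139, 172 and 261 CPM in Week2_WT replicate 1 and Week2_Gata2 replicates 1 and 2, with 0.0541% to 0.0947% of counts on TEC genes, and at 56.8 to 65.2 in the other 3, with 0.201% to 0.316%. All 19 lists that passed at Week2 were higher in the first 3 libraries by their median. Within these, the libraries labelled Gata2 were higher than WT in 17 lists, and within the other 3 in 5, with 4 higher in both; a side holds 1 library of a label, so these counts have no test and were chosen after the data were seen. Within the sides the median log2 differences were 0.19 and -0.11 for monocyte, 0.20 and 0.01 for MHC class II and 0.04 and -0.17 for interferon gamma. These 3 lists passed camera with adjusted p = 0.521 with an estimated correlation. Erythroid genes, lower in 17 of 18 cases (median -1.33), did not pass (adjusted p = 0.0528). Hbb-bs, a beta globin gene, ranged from 11.6 to 3610 CPM in Week2_WT and from 8.78 to 1310 in the libraries labelled Gata2. Without Week2_Gata2 replicate 1 the calls were lost for monocyte (0.925) and interferon gamma lists (0.498), and without Week2_WT replicate 3 for monocyte (0.0683). Medians ranged from 0.09 without Week2_Gata2 replicate 1 to 0.71 without Week2_WT replicate 1 for monocyte. They ranged from 0.18 without Week2_Gata2 replicate 2 to 0.90 without Week2_WT replicate 1 for MHC class II, and from 0.05 without Week2_Gata2 replicate 1 to 0.99 without Week2_WT replicate 1 for interferon gamma.

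In all, 19 of 29 lists passed at Week2 as higher, and 0 with an estimated correlation or by fry. In the simulated Week2 counts the glycolysis list was given a log2 shift of 1. Camera with an estimated correlation did not pass it (adjusted p = 0.254), so the lack of calls by that test is weak evidence against a shift. T and NK cell (median log2 fold change 0.59), stroma (0.42), amino acid stress (0.33), dendritic cell (0.29), p53 target (0.14), immediate early (0.11) and NF-kB genes (0.07, mean -0.09) had adjusted p = 0.521 with an estimated correlation. Cholesterol synthesis (0.34), G2 and mitosis (0.31) and quiescence genes (0.15) had 0.534, ribosome biogenesis (0.28) 0.58, type I interferon (0.30) and repair (0.18) 0.607, oxidative phosphorylation (0.18) 0.678, glycolysis (0.30) 0.695 and S phase (0.16) 0.725. No member passed over all genes or adjusted over the list alone. MHC class II kept its preset call without any 1 library. Of the 19 medians, 15, 17 and 15 moved by over 1.5 times without Week2_Gata2 replicate 1, 2 or 3, to between -0.46 and 0.66, -0.21 and 0.46, and 0.27 and 0.97. Without Week2_WT replicate 1, 2 or 3, 17, 10 and 11 did so, to between 0.26 and 1.20, 0.06 and 0.67, and -0.18 and 0.25. Without Week2_Gata2 replicate 1, S phase, type I interferon and glycolysis passed in the opposite direction (medians -0.12, -0.19 and -0.46), and adjusted p was 0.576 for G2 and mitosis, 0.819 for repair, 0.293 for p53 target, 0.118 for NF-kB and cholesterol, 0.301 for oxidative phosphorylation and 0.883 for ribosome biogenesis and amino acid stress. Without Week2_Gata2 replicate 2 it was 0.732 for dendritic cell, 0.605 for T and NK cell, quiescence and oxidative phosphorylation, 0.988 for stroma, 0.896 for S phase, 0.162 for G2 and mitosis, 0.245 for repair, 0.0567 for p53 target, 0.0955 for NF-kB and 0.134 for ribosome biogenesis. Without Week2_WT replicate 2 it was 0.514 for stroma, 0.591 for S phase, 0.461 for G2 and mitosis, 0.306 for repair, 0.0815 for type I interferon, 0.77 for oxidative phosphorylation and 0.177 for ribosome biogenesis. Without Week2_WT replicate 3 it was 0.172 for T and NK cell, 0.272 for S phase and immediate early, 0.344 for quiescence, 0.0683 for repair, 0.62 for p53 target, 0.876 for type I interferon, 0.182 for NF-kB, 0.235 for oxidative phosphorylation, 0.13 for glycolysis, 0.429 for amino acid stress and 0.0632 for cholesterol. The list count was 11 without Week2_Gata2 replicate 2 and 9 without Week2_WT replicate 3, and stroma lost its call with the share of TEC genes as a covariate (0.151). With that covariate the medians were 0.04 for S phase and p53 target genes, 0.05 for immediate early genes, 0.10 for repair and oxidative phosphorylation, 0.11 for glycolysis, 0.16 for ribosome biogenesis and 0.17 for type I interferon genes. RLE scaling moved 13 medians by over 1.5 times, to between 0.13 and 0.59, and sex as a covariate 14, to between 0.26 and 0.97.

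The other 9 lists at Week2 did not pass. B cell genes had a median log2 fold change of 0.04 (adjusted p = 0.0938), early granulocyte and monocyte progenitor 0.13 (0.803), stem cell ageing 0.11 (0.122), lymphoid priming 0.09 (0.282), stem cell 0.06 (0.225), blood transcription factor partners -0.02 (0.975), late neutrophil granule -0.19 (0.773), megakaryocyte and platelet -0.20 (0.225) and mast cell and basophil 0.01 with a mean of -0.09 and a negative test (0.803). edgeR called 0 of 36485 genes, with 87 at an unadjusted p under 0.05, 1 called by DESeq2 and 12866 by limma voom with quality weights. Sva had the lowest p (log2 fold change 5.37, SE 0.95, adjusted p = 1), with groups that did not overlap. The immunoglobulin gene Ighg3 (7.87, SE 1.76, adjusted p = 1) was at 7.45, 54.6 and 0.134 CPM in Week2_Gata2 replicates 1, 2 and 3, the last within the WT range of 0.0528 to 0.158. There were 4 genes called without Week2_Gata2 replicate 3. The libraries differed within groups: Igha was at 256 to 496 CPM in Week2_WT replicate 1 and Week2_Gata2 replicates 1 and 2, and at 0.407 to 8.49 in the other 3. Groups did not overlap for 1.41% of genes, against 10% by chance.

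The genotype effect at Week2 was also set against that at Day0, although time and cell label change together. Quiescence and immediate early lists had higher differences (median log2 differences 0.29 and 0.17) and S phase a lower one (-0.32) by camera, with adjusted p = 0.972 with an estimated correlation for each. edgeR called 0 of 31164 genes for this difference, with 1459 at an unadjusted p under 0.05, 8 called by DESeq2 and 0 by limma voom. Without Day0_WT replicate 2 it called 3772, and without Day0_WT replicate 1 it called 9.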

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

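The tests of scaling, of exchanged or wrong labels and of cycling cells were chosen after the results were seen; the other tests were set before their results were seen.

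The genotype effect differed between Day2 and Day0, by the test of the difference with camera's preset correlation, in 7 lists, all with a lower effect at Day2. The median log2 differences were -1.16 for glycolysis, -0.958 for late neutrophil granule, -0.66 for cholesterol synthesis, -0.531 for inflammatory NF-kB, -0.487 for unfolded protein and amino acid stress, -0.39 for S phase and -0.317 for oxidative phosphorylation. With an estimated correlation adjusted p was 0.273, 0.785, 0.284, 0.284, 0.428, 0.359 and 0.785 in the same order, and by fry glycolysis and NF-kB passed (adjusted p = 0.0171 each). Between Week2 and Day0 the effect differed in S phase (-0.316), quiescence (0.287) and immediate early genes (0.171), each with adjusted p = 0.972 with an estimated correlation. List tests of these differences were run in the main fits only, without leaving out a library or adding a covariate. At Day0 alone, medians with the TEC share as a covariate were 0.0144 for glycolysis, 0.0239 for cholesterol synthesis, -0.0319 for oxidative phosphorylation and 0.211 for S phase.

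Gata2 was higher in the LSK libraries labelled Gata2, and its lowest log2 fold change over TMM, RLE and upper quartile scaling at Day0 and Day2, 0.734, argued against scaling between libraries. An exchange of 1 pair of libraries was excluded as the whole cause, since the lowest library labelled Gata2 lay above the highest labelled WT by a ratio of 1.37 at Day0 and 1.69 at Day2. With all LSK genotype labels exchanged, the loss of 1 of 2 copies would give a log2 fold change of 1, and the observed values lay within 0.942 SE of it. Exchanged LSK labels with those of Week2 right would part genes by label in opposite directions at Day2 and Week2; after adding 0.1 CPM 1 gene was parted over 4-fold at both, Sva, and in the same direction, but another of the 100 pairs of splits of these libraries gave 1 as well. Exchanged labels and a true rise of Gata2 transcripts, such as from an allele that still makes them, cannot be told apart with the counts of Gata2. Gm37068, with a smaller gap than Sva, also went the same way at both times. It had 0.927 and 1.24 CPM against 0 in each WT library at Day2, and 0.833 to 1.18 against 0.162 to 0.282 at Week2. Both are low genes picked from these same data, so they cannot decide on an exchange in LSK cells alone.

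Glycolysis genes were lower at Day2 in the libraries labelled Gata2. The list's median was -0.748 before and -0.716 after a fit on GC content and exon length, and the higher of the S phase and G2 and mitosis medians was 0.11, which argued against a trend with GC content or gene length and against fewer cycling cells. A lower hypoxia response may account for part of it: 20 hypoxia response genes outside the glycolysis list had a median of -0.609, with 18 lower (p = 0.000522 by camera with an estimated correlation and 0.000249 by fry, 2 tests not adjusted with the lists). Over all genes 0 of the 20 were called. Egln1 (0.289) and Ppfia4 (0.209) were higher, and of the lower genes Ndrg1 (-0.221), Pfkfb4 (-0.199), Car9 (-0.183) and Cited2 (-0.0968) lay within their SE of 0. That list was composed after the Day2 genes of lowest p were known, with those genes left out, and the genotypes' oxygen or culture conditions are not given. A difference in genotype remains open beside it, and it was not tested against handling of the Day2 libraries.

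Day0_WT replicate 1 stood apart from the other Day0 libraries, and lower depth alone was argued against, since the other Day0 libraries thinned to its total kept a lowest pairwise correlation of 0.985, while its own highest with them was 0.865 over the genes of that check. RNA of other marrow cells that raises all 6 lists of such cells was argued against as well. The library's medians against the other Day0_WT library went apart, from -1.06 for late neutrophil granule to 1.18 for stroma. RNA of only some of these cell types stays open, since the test asked for a rise of every list. Monocyte (0.47) and B cell (0.455) medians were also above 0. Loss of transcripts in a library of few molecules stays open: 26 of 9547 genes of 10 CPM or more (0.272%) had no count in it, against 0 to 3 in the thinned libraries, which is above those and below the 1% set beforehand. A wrong genotype label stays open too: at Sva its place between the mean log2 levels of the labels at Day2 and Week2 (0 for WT, 1 for Gata2) was 1.02, against -0.0855 for the other Day0_WT library and 0.928 to 0.998 for those labelled Gata2, and Gm37068 stood at 1.79 CPM against 0.0196 and 1.19 to 1.62, but these are few and low genes, and its Gata2 level (446 CPM) lay below the 611 to 752 of the Day0 libraries labelled Gata2. No biological explanation of this library's difference was tested.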

How the results depend on the processing

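The sex, TEC share, repeat share and protein-coding alternatives were chosen after the data were seen; the others were planned. For each result that changed, the cause was not tested, except where fewer samples or genes enter. Counts of called genes at Day0 were 1 with no low count filter and 417 by DESeq2. At Day2 they were 22 with no low count filter, 1 with 5 CPM in 2 libraries, 144 by DESeq2, 23 by limma voom, 3 with sex, 2 with protein-coding genes, 17 with the TEC share, 3 with the repeat share, 4 with all 16 libraries and 11 with the Day2 libraries alone. At Week2 they were 1 by DESeq2, 12866 by voom and 2 with sex. Over time they were 1355 by voom, 2358 with the TEC share, 173 with the repeat share and 1199 with the libraries of WT alone, and in the libraries labelled Gata2 3471 by DESeq2, 4127 by voom, 5031 with the TEC share and 5676 alone. For the differences they were 2 with no low count filter and 216 by DESeq2 at Day2, and 8 by DESeq2 at Week2.

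With libraries left out in turn, called genes ranged from 0 to 8655 at Day0, 0 to 48 at Day2, 0 to 4 at Week2, 3191 to 12386 in WT over time, 499 to 4863 in the libraries labelled Gata2, 0 to 6733 for the difference at Day2 and 0 to 3772 for that at Week2. Called lists ranged from 5 to 15, 9 to 13, 9 to 25, 15 to 22 and 18 to 24 in the first 5 comparisons. The high values came without Day0_WT replicate 2 (8655, 12386, 6733 and 3772), without Day0_WT replicate 1 (48 and 4863) and without Week2_Gata2 replicate 3 (4). Without Week2_Gata2 replicate 1 the Week2 lists S phase, type I interferon response and glycolysis reversed: their medians ranged from -0.115 to 0.525, -0.189 to 1.03 and -0.458 to 0.765 with 1 library left out, the lowest without that library and the highest without Week2_WT replicate 1. Lists called with an estimated correlation numbered 0 at Day0, 2 at Day2, 0 at Week2, 3 in WT over time and 4 in the libraries labelled Gata2, and by fry 2, 2 and 0 in the first 3.

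Gata2 passed at Day2 with no low count filter (log2 fold change 1.24), DESeq2 (1.20) and voom (1.17), and in WT over time with RLE (-0.618), upper quartile (-0.676), no low count filter (-0.588), 5 CPM in 2 libraries (-0.719), DESeq2 (-0.618) and protein-coding genes (-0.609). With the TEC and the repeat share it was 1.13 and 1.18 at Day0. Over time in WT it was 0.0452 (SE 0.378) and 0.133 (SE 0.387) in the same order. It was 0.147 (SE 0.232) over time with the repeat share in the libraries labelled Gata2. In WT over time these shares turned the direction of Tcf4 (0.256 and 0.333) and Ciita (0.0764 and 0.153). With libraries left out Gata2 ranged from 0.707 to 1.05 at Day0, 0.864 to 1.55 at Day2, -0.304 to 0.682 at Week2, -0.705 to -0.313 in WT over time and -0.494 to 0.0351 in the libraries labelled Gata2. Lists were tested again only with each library left out, RLE scaling, sex, the replicate block, the TEC share, the repeat share (LSK libraries), an estimated correlation and fry. Over these, results of single lists that lost their call or kept it numbered 30 and 106 at Day0, 29 and 158 at Day2 and 80 and 145 at Week2. They numbered 42 and 315 in WT over time and 46 and 345 in the libraries labelled Gata2. Stroma at Week2 had adjusted p = 0.151 with the TEC share, and in WT over time with sex repair had 0.0803 and interferon gamma 0.198; in the libraries labelled Gata2 NF-kB had 0.051 with RLE and 0.0823 with sex.

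Replicate numbers did not pair the libraries: same-numbered libraries had deviations correlated at 0.721, -0.517 and 0.572 at Week2, 0.073 and -0.0954 at Day0, -0.0564 and -0.0317 at Day2. With the replicate block, counts of called genes were 12 at Week2, 789 in WT over time, 141 in the libraries labelled Gata2 and 1 for the difference at Week2, and lists lost were quiescence (0.0896) and immediate early (0.297) at Day0, MHC class II (0.0622) at Day2, interferon gamma (0.0688) in WT over time and NF-kB (0.0672) in the libraries labelled Gata2. At Week2 the splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 0 genes, so all 10 had to give as many and this count cannot decide. The highest other was 20285, for Week2_WT replicate 1 with Week2_Gata2 replicates 1 and 2 against the other 3, which points to a structure of the samples. For lists the real value was 19 and the other splits gave 12 to 22. In all, 7 splits gave as many, the real one included, so the preset list calls at Week2 did not set the genotype split apart.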

Other observations

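The hypoxia list used above was also described in the other comparisons, with no adjustment and chosen after the data were seen. From Day0 to Day2 its median log2 fold change was 1.02 in WT, with 17 of 20 genes higher (9 called higher and 1 called lower). In the libraries labelled Gata2 it was 0.39, with 12 higher (3 called higher and 1 called lower). At Day0 the genotypes differed by 0.03. At Day2 the list included P4ha1, a collagen prolyl hydroxylase gene, at 71.5 CPM (mean, n = 2) in the libraries labelled Gata2 against 159 (n = 3) in WT, and Pdk1, a pyruvate dehydrogenase kinase gene, at 176 against 296. It also included Car9 at 21.1 against 23.9 and Egln1, which was higher, at 21.8 against 17.8.

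At Day0 edgeR called none of the 10 genes of lowest p, with 2586 of all genes at an unadjusted p under 0.05 and 417 called by DESeq2. Among the 10 were Ndn, a growth suppressor gene (4.95 ± 0.782 CPM, SD, n = 3, against 22.3 ± 15.1, n = 2), and Nfkbiz, a gene of the NF-kB pathway (66.3 ± 10.8 against 153 ± 38.3). Slc39a6, a zinc transporter gene (82.6 ± 2.16 against 48 ± 8.8), and Cnn3, an actin-binding protein gene (64 ± 9.46 against 30.8 ± 7.67), were also among them. Rpn1, which lies beside Gata2 on chromosome 6 (88084482 to 88105304, plus strand) and encodes a subunit of oligosaccharyl transferase, was at 539 ± 26.3 against 339 ± 47.1 (log2 fold change 0.67, SE 0.13, adjusted p = 0.341), and its difference between genotypes over time was -0.80 (SE 0.19, adjusted p = 0.465).

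Of 8253 genes at 10 CPM or more in every Day0 library, 7 had no count in any Day2 library: Gprin1 (mean 235 CPM at Day0), n-R5-8s1 (228), Gm24601 (108), Pappa (70.2), Ankrd60 (51.7), Gm12895 (38.8) and Dmp1 (17.7). At Week2 they had counts, for example 59.5 to 133 CPM for Gprin1 and 10.2 to 24.9 for Ankrd60. In the reverse, 0 of 8676 genes at 10 CPM or more in every Day2 library had no count in any Day0 library. Against 3 counts per library, Gprin1 was at least 3830-fold lower in WT and at least 4340-fold lower in the libraries labelled Gata2. Of the 7, n-R5-8s1 and Gm24601 are rRNA genes and Gm12895 is a processed pseudogene. The library kit of each sample is not stated, so a difference in library making or counting between the days was not tested. Any such difference would enter every Day0 to Day2 comparison above, where it cannot be parted from a change in the cells.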
